A study of Mus musculus with 6 samples.

How the data were processed

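Kidney RNA from 6 mice was profiled, 3 wild type and 3 homozygous for a mutation, with 1 array per animal. The series text states that the 3 arrays of a genotype came from different animals, so the spread between them is biological and technical together. Per the labels' protocols, a piece of kidney was frozen after the vessels had been flushed with saline, RNA was purified on silica columns with a DNase step, and biotin-labelled cRNA was made for CodeLink arrays, a single-colour platform with 1 spotted oligonucleotide per probe. The gene that carries the mutation, the strain, the age and the sex of the animals are not given in the sources used here.

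The deposited table held 1 intensity per probe and array on a linear scale, as processed by the authors. Every array had a median between 0.994 and 0.997, and values ran from -1.02 to 951, so the intensities were background-subtracted and already divided by an array-wide level close to the median. That reading comes from the values, since the software, the background method and the scaling step are not given in the sources used here. Between 207 and 255 of the 34937 probes had no value on an array, and between 2.66% and 3.46% of the values of an array were 0 or negative. Negative values have no logarithm, so subtraction of background makes the dimmest probes the noisiest and removes some of them.

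Each array was divided by its own median, values at or below 0 were treated as missing, values under the 10th percentile of all positive values (0.290 of the array median) were set to that floor, and log2 was taken. Probes with a value on at least 2 arrays of each genotype numbered 34445, and after the lowest 25% of these by mean log2 level were left out, 25834 were tested. Gene symbols came from the platform annotation. It gave 1 symbol to 21590 probes, several to 681 and none to 12666, and probes of the last 2 kinds were tested without being named. Of the probes with 1 symbol, 21462 matched the mouse RefSeq gene table (GRCm38.p6) through the gene identifier, and 0 symbols needed updating. Positions in the genome were not used here. For genes with several tested probes, the probe with the highest mean level stood for the gene, which left 14817 genes.

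Genotypes were compared with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with an intensity trend in the prior variance, two-sided, as mutant minus wild type. P-values were adjusted over the 25834 probes by the Benjamini-Hochberg method, and a gene is said to have risen or fallen only past an adjusted p of 0.05. Errors of differences are the standard errors of that fit, and errors of group levels are SDs over 3 arrays. The number of arrays limits the precision. The same code was tested on simulated arrays that kept the means and spreads of the 25834 probes, with 50 probes changed at each size. Of changed probes above the low-signal limit, 6 of 26 were recovered at 1 log2 unit, 18 of 27 at 2 units and 29 of 29 at 3 units. Below that limit, 6 of 21 were recovered at 3 units, and 1 unchanged probe was called in the whole simulation. Few probes were changed, so the adjustment was stricter there than in the data. Noise was drawn separately for each probe, so noise shared between probes was not simulated.

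Array files without background flags give no direct test of detection. A low-signal limit was therefore set after the values had been seen, at the mode of the linear values (0.525 of the array median) plus 3 times the spread of the values below the mode (0.331), which comes to 1.52 times the array median, or 0.60 in log2. Where all arrays of a genotype, or the mean of a named gene, lay below the limit, the difference is given as "at least N-fold", the mean of the brighter genotype over the limit.

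Before the data were examined, the test, the filters, the processing alternatives, 44 gene lists for kidney segments, other cell types and pathways, and the rule for genes named in the text were fixed. That rule took, per direction, the 15 genes with the largest difference among those past the threshold whose groups did not overlap, up to 4 members per list by smallest p, 3 genes of the highest level, and probes of Xist and of Y-linked genes. Other genes are named only where a small count called for it, and the text says so. List shifts were tested with camera of limma with a preset inter-gene correlation of 0.01 over members measured on all 6 arrays, for the 43 lists with at least 5 such members, and adjusted over the lists by the Benjamini-Hochberg method. Camera with an estimated correlation and fry were run beside it. For each list, members past the threshold were counted over all probes and again adjusted over the list alone.

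Alternatives covered quantile and cyclic loess scaling, no further centring, no floor or a pseudocount of 0.5, other filters on dim or missing probes, other variance models, array weights, a replicate block, other thresholds, other list tests, and leaving out each array in turn. Further alternatives were chosen after the data had been seen, among them a term for replicate 1 of both genotypes, a fit on replicates 2 and 3 alone, and a filter at the low-signal limit. Every column of the table belonged to a sample, and no array was left out of the main comparison.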

Results

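Kidney transcripts of 3 wild-type mice and 3 mice homozygous for a mutation were measured on 6 single-colour oligonucleotide arrays, 1 per animal. The design asks which transcripts differ in abundance between the 2 genotypes. Because the mutated gene is not given in the sources used here, its own transcript could not be set against the labels. Levels are log2 intensities relative to the array median, and differences are mutant minus wild type with the SE of the limma fit, n = 3 arrays per genotype, or 2 in wild type for Egr2, Ifi47, Fga, Jun and Cys1 and 2 in mutants for Alas2, which lacked a value on 1 array. Between 37.5% and 41.7% of the values of an array lay above the low-signal limit of 0.60 log2. The median SD of a probe over the 3 arrays was 0.34 log2 in wild type and 0.31 log2 in mutants.

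Mutant kidneys had higher transcript levels of many tubular injury, extracellular matrix, antigen presentation and myeloid genes (16 of 27, 31 of 33, 10 of 13 and 13 of 29 measured), and lower levels of some genes of the proximal tubule (11 of 31), of gluconeogenesis and amino acid catabolism (15 of 37) and of fatty acid oxidation (6 of 28). By camera, 0 of 43 lists passed with an estimated correlation. The counts of decreases were smaller in several fits that lacked 1 array. They numbered 11, 11 and 7, in the order above, without wild-type replicate 1. Such fits have fewer arrays and also unbalance the sex-linked pattern of replicate 1, described below. The cause of the changes was not tested. Proximal tubule genes lower numbered 6 without wild-type replicate 3 and 4 without mutant replicate 2. Those of amino acid catabolism numbered 6 to 8 without any array other than wild-type replicate 1. Those of fatty acid oxidation numbered 3 without wild-type replicate 2 or 3 or mutant replicate 2. Over the alternatives, the medians of these lists stayed between -0.71 and -0.59, -0.63 and -0.52, and -0.47 and -0.28, in that order. Havcr1, the kidney injury molecule shed by damaged proximal tubules, lay below the low-signal limit on the 3 wild-type arrays and at 4.98 ± 0.0066 log2 (SD, n = 3) in mutants, which was at least 20.8-fold higher (limma, adjusted p = 7.0e-07). Timp1, an inhibitor of matrix metalloproteinases, was at least 9.79-fold higher, and Fn1, which encodes fibronectin, rose by 1.99 ± 0.13 log2 units. Sucnr1, the succinate receptor, fell by 2.10 ± 0.21 log2 units, and Aadat, an aminotransferase of lysine and tryptophan breakdown, fell by 1.67 ± 0.19. Of 14817 genes tested, 840 rose and 235 fell. With no intensity trend in the variance, 143 rose and 6 fell, and Aadat did not pass. Genes higher in mutant kidney numbered 526 without homozygous mutant replicate 1 and 476 without homozygous mutant replicate 2, and genes lower numbered 113 to 152 without wild-type replicate 2 or 3 or mutant replicate 2 or 3.

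Across all probes, 1063 rose and 329 fell of 25834 tested (limma with Benjamini-Hochberg adjustment), so that 76.4% of the 1392 calls were higher in mutants. That share was 61.2% after quantile normalization and 63.4% after cyclic loess. With no intensity trend in the variance, 191 probes passed, 179 higher in mutant kidney and 12 lower. Of the 126 named genes that passed, 84 did not with no intensity trend, 3 with robust variance and 33 with only replicates 2 and 3 of each genotype. With only replicates 2 and 3 of each genotype, 905 passed, of which 630 were higher in mutant kidney. Left out in turn, single arrays moved the number of probes past the threshold to 881 without homozygous mutant replicate 1 and to 743 without homozygous mutant replicate 2. Probes lower in mutant kidney then numbered 214 and 154, against 210 without homozygous mutant replicate 3, 204 without wild type replicate 2 and 167 without wild type replicate 3. The groups did not overlap in 5344 of the 22989 probes measured on all 6 arrays (23.2%), against 10% by chance. Among genes past the threshold, 511 differed at least 2-fold upwards and 63 downwards in the fitted values, or 452 and 56 where genes below the low-signal limit stood at their bound. At least 4-fold, the fitted counts were 120 and 4, and with bounds 66 and 1. The 1 gene in that last count was Sucnr1.

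Among the largest increases Krt20, a keratin of surface epithelia, was at least 10.4-fold higher. Aoc1, a diamine oxidase, was above the limit on all arrays and rose by 3.61 ± 0.16, or 12.3-fold, from 2.67 ± 0.25 to 6.29 ± 0.18 (SD, n = 3 each), with the smallest adjusted p of the comparison (limma, 6.6e-08). Ubd, a ubiquitin-like protein induced by cytokines, was at least 11.7-fold higher. Among chemokine genes Ccl5 rose by 3.26 ± 0.58, although not with robust variance or with no intensity trend in the variance (limma, adjusted p = 0.213 and 0.155, against at most 0.0258 in the other alternatives), while Cxcl1 was at least 6.66-fold, Ccl12 at least 4.39-fold, Ccl9 at least 3.62-fold and Cxcl2 at least 2.64-fold higher. The wild-type means of Krt20, Ubd, Cxcl1 and Ccl12 lay below the low-signal limit, with 1 of 3 arrays above it. Among genes below the limit in wild type, Retnla was at least 6.27-fold higher, a bound of 3.29 without mutant replicate 1, and did not pass with robust variance or with no intensity trend in the variance (limma, adjusted p = 0.115 and 0.122, against at most 0.0119 in the other alternatives). Egr2 was at least 5.73-fold, B3galt1 at least 3.22-fold and Mybpc2 at least 2.90-fold higher. Ccl12 and B3galt1 also did not pass with no intensity trend in the variance. Serpina10, with a wild-type mean below the limit and 2 of 3 arrays above it, was at least 12.2-fold higher. Second probes of Serpina10 and B3galt1 had means below the limit in both genotypes and test neither call.

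The largest decreases were smaller than the largest increases. Besides Sucnr1 and Aadat, the carboxylesterase Ces1e fell by 1.71 ± 0.21 log2 units, the apolipoprotein Apom by 1.60 ± 0.20 and the carboxylate transporter family member Slc16a4 by 1.51 ± 0.28. Aldh6a1, a dehydrogenase of valine breakdown, was 2.83-fold lower. Further genes were read against a mutant signal below the limit: Akr1d1, at least 1.90-fold lower, Mylk3, at least 1.48-fold, Gm15318, at least 1.69-fold, and Cd200r2, at least 1.31-fold. Cnot4 was at least 1.94-fold lower, with a second probe below the limit in both genotypes. The apolipoprotein Apoa2, above the limit on 1 of 3 mutant arrays and below it in their mean, was at least 2.21-fold lower. With no intensity trend in the variance, only Sucnr1 and Aldh6a1 among these decreases kept their call. Some calls were also lost in limma fits without 1 array. Cd200r2 had an adjusted p of 0.0559 without wild-type replicate 1 and 0.0769 without wild-type replicate 3, and Gm15318 had 0.0639 without wild-type replicate 3 and 0.0508 without mutant replicate 2. Without wild-type replicate 1, wild-type replicate 3 or mutant replicate 2 the adjusted p lay between 0.0532 and 0.0595 for Cnot4 and between 0.0591 and 0.0713 for Apoa2. The 3 named genes with the highest level, Fth1, Gpx3 and Fxyd2, differed by -0.16 ± 0.26, -0.38 ± 0.26 and -0.35 ± 0.27 and did not pass.

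**Figure D1:**
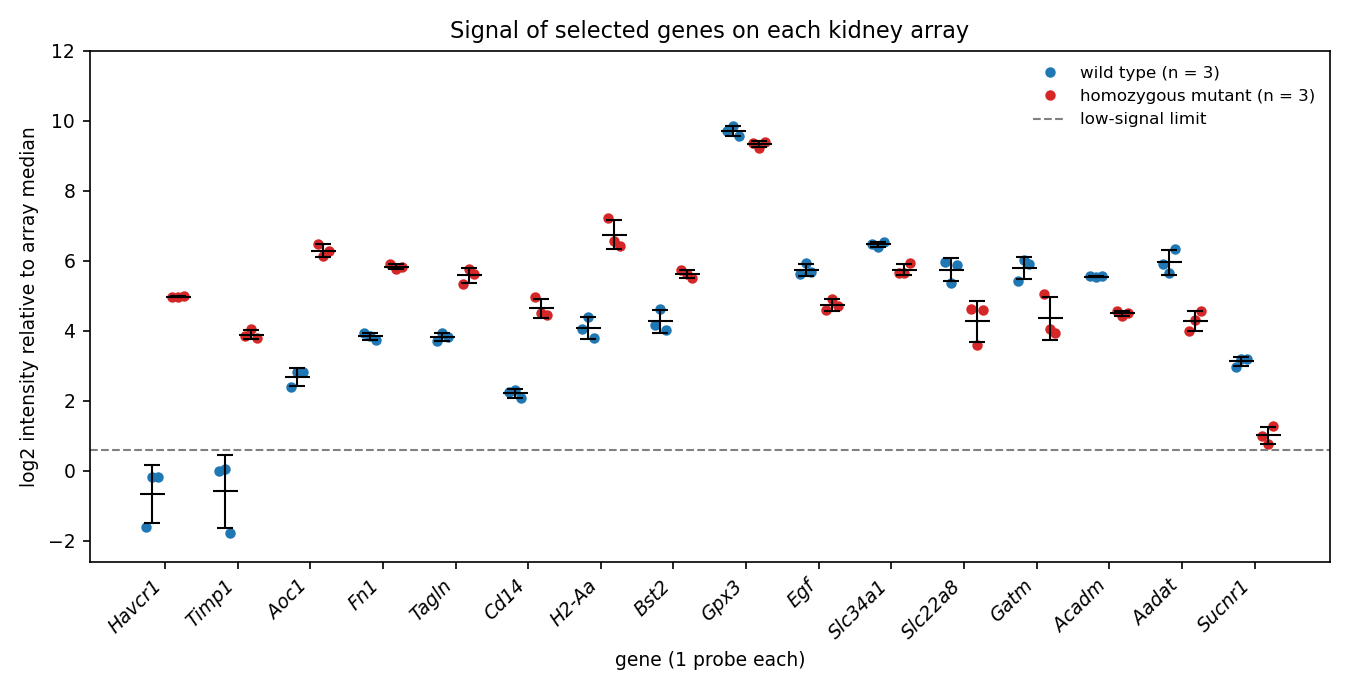
Log2 intensity relative to the array median (y axis) of 16 genes (x axis) on each of the 6 kidney arrays, with wild type in blue and homozygous mutant in red, the mean as a wide bar and the SD as error bars (n = 3 each). Havcr1 and Timp1 lie below the dashed low-signal limit on the 3 wild-type arrays, and Sucnr1 shows the largest of the decreases drawn, 2.10 log2 units downwards.

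Among tubular injury genes, 16 of 27 measured members rose and 0 fell, or 17 and 0 adjusted over the list alone, and 1 fell without mutant replicate 1. Beside Havcr1, Krt20 and Timp1, the adhesion molecule Icam1 rose by 1.80 ± 0.14 log2 units and Anxa1, an annexin that dampens inflammation, by 1.85 ± 0.15. The list shifted upwards (camera with Benjamini-Hochberg, adjusted p = 9.9e-13), with adjusted p = 0.082 with an estimated correlation, and its median member differed by 1.16, or 1.05 with bounds. Of 27 immediate early and stress kinase genes, 7 rose and 0 fell, or 11 and 0 adjusted over the list alone, but 3 rose without wild-type replicate 1 or 3 or mutant replicate 1 or 2. They included Egr2, the matricellular gene Ccn1 (1.45 ± 0.19) and the transcription factor gene Jun (0.98 ± 0.18). For this list camera gave an adjusted p of 0.010, and adjusted p = 0.142 with an estimated correlation.

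Matrix genes moved nearly as a block, with 31 of 33 measured members of the fibrosis and extracellular matrix list higher and 0 lower, or 32 and 0 adjusted over the list alone. Mgp, a matrix protein that inhibits calcification, rose by 2.60 ± 0.17 log2 units, or 6.06-fold. Loxl1, a cross-linking oxidase, rose by 2.24 ± 0.15, and the membrane-bound metalloproteinase Mmp14 by 1.93 ± 0.17. The median member differed by 1.93, or 1.81 with bounds (camera, adjusted p = 4.1e-35), with adjusted p = 0.082 with an estimated correlation. Of 14 smooth muscle, pericyte and juxtaglomerular genes, 9 rose and 0 fell, or 12 and 0 adjusted over the list alone. The actin-binding Tagln rose by 1.76 ± 0.14, the pericyte receptor Pdgfrb by 1.35 ± 0.17, the smooth muscle myosin Myh11 by 1.05 ± 0.16 and desmin (Des) by 1.48 ± 0.26. For that list camera gave an adjusted p of 1.6e-09, and adjusted p = 0.082 with an estimated correlation.

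Immune genes rose in several lists. Of 13 antigen presentation genes, 10 rose and 0 fell, or 12 and 0 adjusted over the list alone (camera, adjusted p = 2.8e-13), with adjusted p = 0.142 with an estimated correlation. The median member differed by 1.78, or 1.30 with bounds. The class II genes H2-Aa, H2-Ab1 and H2-Eb1 and their invariant chain Cd74 rose by between 2.45 ± 0.15 and 2.66 ± 0.20 log2 units. Of 29 macrophage and myeloid genes, 13 rose and 0 fell, or 17 and 0 adjusted over the list alone (camera, adjusted p = 7.9e-11), with adjusted p = 0.102 with an estimated correlation. The median member differed by 1.13, or 0.79 with bounds, and 12 of 29 lay below the low-signal limit in a genotype. The lipopolysaccharide co-receptor Cd14 rose by 2.42 ± 0.17, the protease Ctss by 2.52 ± 0.19, and the complement genes C1qa and C1qc by 2.26 ± 0.16 and 2.38 ± 0.19. Of 27 interferon response genes, 14 rose and 0 fell, or 17 and 1 adjusted over the list alone (camera, adjusted p = 1.1e-07), with adjusted p = 0.296 with an estimated correlation, and 8 rose without mutant replicate 1. Examples were the tethering factor Bst2 (1.35 ± 0.16), Ifi47 (1.52 ± 0.18), Oasl2 (1.66 ± 0.22) and the chemokine Cxcl10, at least 4.31-fold higher with a wild-type mean below the low-signal limit.

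Complement and lymphocyte lists also shifted upwards by camera. Of 17 complement and coagulation genes, 6 rose and 0 fell, or 8 and 0 adjusted over the list alone. The C1 inhibitor Serping1 rose by 2.15 ± 0.17 log2 units, C1ra by 1.64 ± 0.14 and tissue factor (F3) by 1.10 ± 0.18, while the fibrinogen chain Fgg was at least 4.11-fold higher. Camera gave an adjusted p of 0.012, which was 0.0823 without mutant replicate 1, and adjusted p = 0.337 with an estimated correlation. Of 24 T, B and NK lymphocyte genes, 3 rose and 0 fell, or 6 and 0 adjusted over the list alone. These were Ccl5, which did not pass with robust variance or with no intensity trend in the variance, Ighm (1.19 ± 0.18), whose other 2 probes differed in the same direction without passing, and the T cell receptor component Cd3d, at least 2.38-fold higher with a wild-type mean below the low-signal limit. After quantile normalization or cyclic loess Cd3d did not pass, and without wild-type replicate 2 or 3 or mutant replicate 1 or 3 it had a limma adjusted p between 0.0588 and 0.134. Camera gave the lymphocyte list an adjusted p of 0.046, which was between 0.0767 and 0.163 without wild-type replicate 2 or 3 or mutant replicate 1, and adjusted p = 0.471 with an estimated correlation. The list also did not pass with no filter on dim probes. Its median member differed by 0.61, or 0 with bounds, and 15 of 24 lay below the low-signal limit in a genotype.

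Of 31 measured proximal tubule genes 11 fell and 0 rose, or 24 and 0 adjusted over the list alone, and the difference was negative in all 31. Without wild-type replicate 3 the number lower was 6, and without mutant replicate 2 it was 4. The organic anion transporter Slc22a8 fell by 1.48 ± 0.24 log2 units, Gatm, the first enzyme of creatine synthesis, by 1.44 ± 0.25, and the transcription factor Hnf4a by 0.76 ± 0.15. The phosphate transporter Slc34a1 fell by 0.72 ± 0.14, with a limma adjusted p of 0.0507 without wild-type replicate 3 and 0.0558 without mutant replicate 2. The median member differed by -0.64 (camera, adjusted p = 1.6e-19), with adjusted p = 0.082 with an estimated correlation.

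Metabolic lists followed the same direction. Whether these falls, and those of the citric acid cycle and oxidative phosphorylation below, were separate from the proximal tubule fall was not tested. Of 37 genes of gluconeogenesis and amino acid catabolism 15 fell and 0 rose, or 23 and 0 adjusted over the list alone (camera, adjusted p = 3.0e-14), with adjusted p = 0.0559 with an estimated correlation. Between 6 and 8 fell in each fit that lacked an array other than wild-type replicate 1. Kmo, of the kynurenine pathway, fell by 1.27 ± 0.15 log2 units, Prodh, which oxidises proline, by 0.73 ± 0.13, Sardh, which oxidises sarcosine, by 0.74 ± 0.14, and Gldc, of glycine cleavage, by 1.04 ± 0.20. A second Gldc probe differed by -0.84 ± 0.33 and did not pass. Of 28 genes of fatty acid oxidation and PPAR alpha targets 6 fell and 0 rose, or 9 and 0 adjusted over the list alone (camera, adjusted p = 1.9e-08), with adjusted p = 0.142 with an estimated correlation. Without wild-type replicate 2 or 3 or mutant replicate 2, 3 fell, and 1 rose without wild-type replicate 2. The medium-chain dehydrogenase Acadm fell by 1.05 ± 0.12, the peroxisomal enzyme Ehhadh by 0.95 ± 0.14 and the fatty acid hydroxylase Cyp4a14 by 1.01 ± 0.18.

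The lists of the citric acid cycle and of oxidative phosphorylation also shifted downwards. Of 23 citric acid cycle genes 4 fell and 0 rose, or 11 and 0 adjusted over the list alone, with a negative difference in all 23 and a median of -0.38 (camera, adjusted p = 4.0e-11), and adjusted p = 0.154 with an estimated correlation. Those 4 were Idh1 (-1.11 ± 0.24), Sdha (-0.78 ± 0.19), Me1 (-0.72 ± 0.18) and Sdhc (-0.55 ± 0.13). Idh1 and Me1, which the list included, encode cytosolic enzymes. Of 50 genes of oxidative phosphorylation 3 fell and 0 rose, also 3 and 0 adjusted over the list alone, with a positive difference in 1 and a median of -0.24 (camera, adjusted p = 2.5e-10), and adjusted p = 0.337 with an estimated correlation and 0.0835 by fry. The 3 were Sdha and Sdhc, already counted in the citric acid cycle list, and the complex I subunit Ndufa9 (-0.51 ± 0.14). With arrays left out in turn, Idh1 was lost without wild-type replicate 2 or 3 or mutant replicate 2 or 3, and Sdha without wild-type replicate 1 or any of the mutants. Me1 and Sdhc held only without wild-type replicate 1, and Ndufa9 in none of the 6 cases. The limma adjusted p of these losses lay between 0.0548 and 0.181.

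Lists of drug-handling, female-biased and male-biased kidney genes shifted downwards by camera but did not pass by fry (adjusted p = 0.0944, 0.0516 and 0.229). Of their members, 13 of 37, 8 of 14 and 9 of 17 also stood in another list. These shifts are thus not fully independent of the others, and none was tested without the shared members. Of 37 genes of xenobiotic metabolism and transport 10 fell and 1 rose, or 14 and 4 adjusted over the list alone (camera, adjusted p = 3.4e-05), with adjusted p = 0.142 with an estimated correlation. Without any array other than wild-type replicate 1, 5 or 6 fell, and 4 rose without wild-type replicate 2. The organic anion carrier Slco1a6 fell by 1.36 ± 0.16 log2 units, the monooxygenase Fmo1 by 1.12 ± 0.18 and the efflux pump Abcg2 by 0.99 ± 0.15, whereas the cytochrome Cyp1b1 rose by 1.96 ± 0.18. Of 14 genes known to be higher in female mouse kidney 5 fell and 0 rose, or 7 and 0 adjusted over the list alone (camera, adjusted p = 5.1e-05), with adjusted p = 0.082 with an estimated correlation. They were Hao2 (-1.24 ± 0.17), Cyp4a14, Sult1d1 (-0.91 ± 0.21), Slc22a7 (-0.96 ± 0.24) and Acsm2 (-0.82 ± 0.21), the last named after its value was seen. Of 17 genes known to be higher in male mouse kidney 1 fell, Mep1a (-0.69 ± 0.17), and 1 rose, Gusb (0.71 ± 0.19), or 5 and 2 adjusted over the list alone (camera, adjusted p = 0.0055), with adjusted p = 0.330 with an estimated correlation. The number of female-biased genes lower was 2 or 3 without any array other than wild-type replicate 1. Male-biased genes numbered 3 lower and 0 higher without wild-type replicate 1, and 0 lower and 2 higher without wild-type replicate 2. Leaving out an array unbalances the sex-linked pattern of replicate 1, described below, between genotypes. Counts from such fits therefore mix that pattern with genotype. In fits without 1 array each, Sult1d1 was lost without wild-type replicate 2 or 3 or mutant replicate 3, and Mep1a held only without wild-type replicate 1 or mutant replicate 3. Slc22a7 held only without wild-type replicate 3, Gusb only without wild-type replicate 2 and Acsm2 only without wild-type replicate 1. A second Slc22a7 probe differed by -1.76 ± 0.53 and did not pass. Slc22a7 was also lost with robust variance, array weights, no floor or stricter filters on dim probes. Where a call was lost, the limma adjusted p lay between 0.0625 and 0.171, and Gusb did not pass after quantile normalization or cyclic loess.

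**Figure D2:**
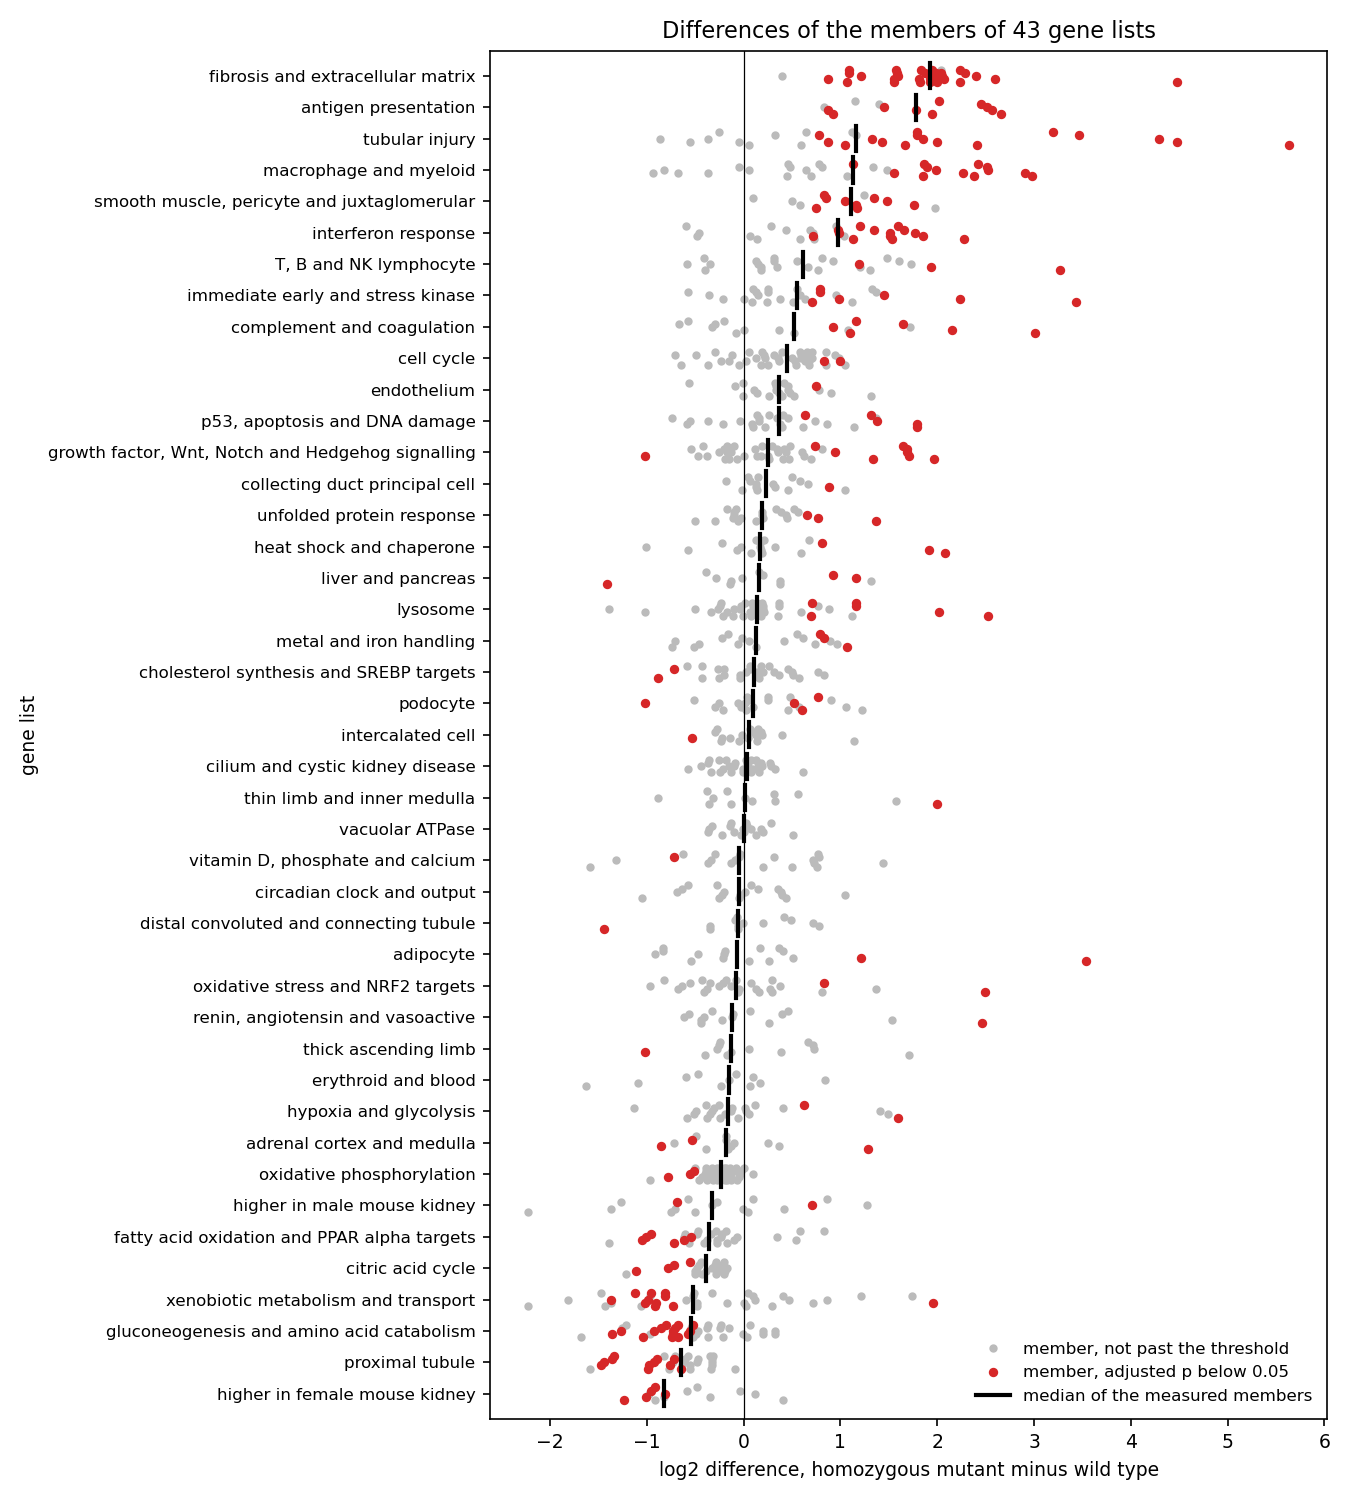
Log2 difference, homozygous mutant minus wild type (x axis), of each measured member of 43 gene lists (y axis), in red where the adjusted p was below 0.05 and in grey otherwise, with a black bar at the median of the list. Fibrosis and extracellular matrix lies at 1.93 at one end and the list of genes higher in female mouse kidney at -0.82 at the other.

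Endothelial, cell cycle and p53 lists shifted upwards by camera with few single calls. Of all tested genes 5.67% rose, so the calls in the endothelial and cell cycle lists were no excess over that share. Of 21 endothelial genes 1 rose, the receptor Tie1 (0.74 ± 0.19), and 0 fell, or 4 and 0 adjusted over the list alone (camera, adjusted p = 0.016), with adjusted p = 0.396 with an estimated correlation. The limma adjusted p of Tie1 lay between 0.0945 and 0.141 without wild-type replicate 1 or 3 or mutant replicate 1 or 2, and 2 endothelial genes rose without wild-type replicate 2 or mutant replicate 3. Of 42 cell cycle genes 2 rose, Ccnd2 (0.99 ± 0.19) and Mcm3 (0.83 ± 0.21), and 0 fell, also 2 and 0 adjusted over the list alone, against 7 risen without wild-type replicate 3 and 1 without any other array. Camera gave that list an adjusted p of 0.038 (0.342 by fry), which was between 0.168 and 0.452 without wild-type replicate 1 or 2 or mutant replicate 3, and adjusted p = 0.674 with an estimated correlation. Of 28 genes of p53, apoptosis and DNA damage 5 rose and 0 fell, or 6 and 0 adjusted over the list alone, against 2 or 3 risen without wild-type replicate 3 or any of the mutants. They were Pmaip1 (1.32 ± 0.21), Phlda3 (1.38 ± 0.24), Zmat3 (0.64 ± 0.13), the cell cycle inhibitor Cdkn1a, at least 1.56-fold higher, and the inflammatory caspase Casp1, at least 1.75-fold higher and named after its value was seen. For that list camera gave an adjusted p of 0.029, which was 0.0528 without wild-type replicate 2 and 0.163 without mutant replicate 1, and adjusted p = 0.484 with an estimated correlation. The median p53 list member differed by 0.36, or 0.16 with bounds, and 11 of 28 lay below the low-signal limit in a genotype. With only replicates 2 and 3 of each genotype, neither the cell cycle nor the p53 list passed. Across the 6 fits that lacked an array, Mcm3 held only without wild-type replicate 3 and Casp1 only without wild-type replicate 2, and neither passed after quantile normalization or cyclic loess. Cdkn1a was lost without any of the mutants and Zmat3 without wild-type replicate 3 or mutant replicate 1 or 2. These losses had a limma adjusted p between 0.0522 and 0.228.

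Distal nephron, collecting duct, podocyte and inner medulla lists did not pass (camera, adjusted p between 0.164 and 0.800). In the thick ascending limb list Egf, a growth factor precursor of that segment, fell by 1.02 ± 0.14 log2 units as the 1 call of 13, and in the distal convoluted and connecting tubule list Pvalb, a calcium buffer, fell by 1.44 ± 0.25 as the 1 call of 13. In the principal cell list 1 of 16 rose, Kcne1 (0.88 ± 0.20), in the intercalated cell list 1 of 18 fell, Car12 (-0.53 ± 0.14), and in the thin limb and inner medulla list 1 of 13 rose, S100a6 (2.00 ± 0.17). Of 23 podocyte genes 3 rose, Cd2ap (0.61 ± 0.14), Cdkn1c (0.52 ± 0.13) and Lamb2 (0.77 ± 0.20), and 1 fell, the basement membrane collagen Col4a3 (-1.02 ± 0.24). Adjusted over the list alone, 6 podocyte genes rose and 1 fell, in the distal convoluted list 2 rose and 1 fell, and the other 4 lists kept 1 call each. When each array was left out, Kcne1 held only without wild-type replicate 3, Car12 only without wild-type replicate 1, Lamb2 only without mutant replicate 3 and Cdkn1c in none of the 6 cases. Cd2ap was lost without wild-type replicate 3 or mutant replicate 1 or 2, and Col4a3 without wild-type replicate 1 or mutant replicate 3. The limma adjusted p of these losses lay between 0.0510 and 0.202. After quantile normalization or cyclic loess Cdkn1c and Lamb2 did not pass.

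Among the other lists without a shift (camera, adjusted p between 0.155 and 0.860), growth factor, Wnt, Notch and Hedgehog signalling had 8 risen and 1 fallen of 42 genes, or 9 and 2 adjusted over the list alone, with 5 risen without any of the mutants and 2 fallen without wild-type replicate 3. The secreted Dkk3 rose by 1.69 ± 0.17 log2 units, Tgfb3 by 1.70 ± 0.20 and Bmp2 by 1.34 ± 0.23, and Egf fell. Second probes of Tgfb3 and Bmp2 had means below the low-signal limit but lay above it on 3 and 1 of 6 arrays. Neither passed (limma, adjusted p = 0.951 and 0.0556). Of 41 lysosome genes 6 rose and 0 fell, or 8 and 1 adjusted over the list alone, but 3 rose and 1 fell without mutant replicate 1, with the membrane protein Scarb2 at 1.16 ± 0.12 and the protease Ctsc at 1.16 ± 0.20, of whose other 2 probes 1 lay below the low-signal limit in both genotypes. In the heat shock and chaperone list 3 of 18 rose, or 4 adjusted over the list alone: the small heat shock genes Hspb1 (2.08 ± 0.23) and Hspb8 (1.91 ± 0.26), and Hspa1b (0.81 ± 0.21). The unfolded protein response list had 3 of 22, or 4 adjusted over the list alone: Asns (1.37 ± 0.24), Atf5 (0.77 ± 0.19) and Ddit3 (0.66 ± 0.17). With arrays left out in turn, Hspa1b held only without wild-type replicate 2 or mutant replicate 3, Atf5 only without wild-type replicate 1 and Ddit3 only without wild-type replicate 2, and the losses had a limma adjusted p between 0.0549 and 0.189. Atf5 and Ddit3 did not pass after quantile normalization or cyclic loess. Hspa1b was also lost with no floor, with a pseudocount of 0.5 and with stricter filters on dim or missing probes.

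Stress and metal genes gave few calls. In the oxidative stress list 2 of 27 rose, also 2 up and 1 down adjusted over the list alone: the aldo-keto reductase Akr1b8 (2.49 ± 0.21) and haem oxygenase Hmox1 (0.83 ± 0.21). In the metal and iron list 3 of 19 rose, or 5 up and 1 down adjusted over the list alone: transferrin (Trf, 1.07 ± 0.17), metallothionein Mt1 (0.79 ± 0.20) and Hmox1. The hypoxia and glycolysis list had 2 of 24 risen, or 3 adjusted over the list alone, Pfkp (0.62 ± 0.14) and Hk2, at least 1.96-fold higher with a wild-type mean below the low-signal limit. In the renin, angiotensin and vasoactive list 1 of 15 rose, the vasoconstrictor precursor Edn1, at least 2.81-fold higher, or 2 up and 1 down adjusted over the list alone. Of 28 cholesterol synthesis genes 2 fell, Acss2 (-0.88 ± 0.13) and Me1, or 3 down and 2 up adjusted over the list alone. In the vitamin D, phosphate and calcium list Slc34a1 was the 1 decrease of 20, or 1 down and 4 up adjusted over the list alone. In fits without 1 array each, Hmox1 held only without wild-type replicate 2, Hk2 only without wild-type replicate 3, Me1 only without wild-type replicate 1 and Mt1 only without wild-type replicate 2 or mutant replicate 3. Pfkp and Slc34a1 were lost without wild-type replicate 3 or mutant replicate 2. Where a call was lost, the limma adjusted p lay between 0.0501 and 0.158, and Hmox1 did not pass after quantile normalization.

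No member passed in the lists for the cilium and cystic kidney disease (32 measured), the vacuolar ATPase (18), the circadian clock (18) or blood cells (11), with 0 also adjusted over the list alone, except for 1 circadian gene that fell without wild-type replicate 3 and, in limma, the smallest adjusted p of 0.282 (Cys1), 0.137 (Atp6v0a1), 0.0748 (Hlf) and 0.229 (Alas2). As a check for contaminating tissue, the adipocyte, adrenal and liver and pancreas lists did not shift (camera, adjusted p = 0.860, 0.155 and 0.511). The adipocyte list had 2 of 16 risen, Retnla and the lipid droplet gene Cidec (1.21 ± 0.16), also 2 adjusted over the list alone. The adrenal list had 1 of 13 risen, the neuropeptide Npy (1.28 ± 0.31), and 2 fallen, Ddc (-0.85 ± 0.21) and Fdx1 (-0.54 ± 0.14), the same numbers adjusted over the list alone. The liver and pancreas list had 2 of 13 risen, the fibrinogen chains Fga (1.16 ± 0.20) and Fgb (0.92 ± 0.20), and 1 fallen, Apoa2, again the same numbers adjusted over the list alone. Fga and Fgb also stood in the complement and coagulation list, and Ddc in that of amino acid catabolism. Those calls are therefore not specific to such tissue. Across the 6 fits that lacked an array, Fdx1 held only without wild-type replicate 2, Npy only without wild-type replicate 1 or 2 and Fgb only without wild-type replicate 1 or mutant replicate 2. Ddc and Apoa2 were lost without wild-type replicate 1, wild-type replicate 3 or mutant replicate 2. These losses had a limma adjusted p between 0.0511 and 0.125.

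Of the 43 lists tested, 20 shifted by camera with the preset correlation, 12 upwards and 8 downwards, 15 passed by fry, 14 of them among the 20, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.0559. By camera, other splits of the 6 arrays into 3 and 3 gave up to 17 lists, so the counts of members carry more weight than the list tests. Of the 20, those lost by fry were oxidative phosphorylation, the xenobiotic, female-biased and male-biased lists, cell cycle and the lymphocyte list (adjusted p between 0.0516 and 0.342). Of the other 23 lists, heat shock passed without wild type replicate 2 (camera, adjusted p = 0.0219), lysosome without homozygous mutant replicate 2 (0.0493), and metal and iron handling by fry (0.0156). Left out singly, some arrays also gave decreases where none stood in the full fit: 1 in oxidative stress (wild-type replicate 1 or 2), 1 each in metal handling and renin and 2 in hypoxia (wild-type replicate 1). Increases of 1 appeared likewise in thick ascending limb (wild-type replicate 3), distal convoluted tubule (wild-type replicate 2 or mutant replicate 3) and vitamin D (wild-type replicate 2 or 3 or mutant replicate 3). The signs of median, mean and test differed for 9 lists, none of them shifted: thick ascending limb, oxidative stress, cilium, renin, cholesterol synthesis, vacuolar ATPase, intercalated cell, hypoxia and adipocyte.

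Arrays of a genotype resembled each other more than arrays of different genotypes. Over 22989 probes measured on all 6 arrays, Pearson's r across probes averaged 0.937 within genotypes (0.926 to 0.946) and 0.918 between them (0.905 to 0.933). Of the 10 splits into 3 and 3, the real one gave the largest gap, 0.0183, for an exact two-sided permutation p of 0.1, the smallest this design allows. The first principal component held 33.5% of the variance, with wild-type arrays at -71.4, -30.7 and -28.0 and mutant arrays between 35.9 and 47.4. The second held 20.8%, with replicate 1 at 54.0 in wild type and 36.9 in mutants. Replicates 2 and 3 lay at -43.0 and -38.9 in wild type and at 2.43 and -11.5 in mutants.

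Transcripts linked to sex separated replicate 1 of each genotype from the other animals. The Xist probe read 4.64 times the array median in wild-type replicate 1 and 7.98 in mutant replicate 1, against 0.556 to 0.862 on the other 4 arrays. A second Xist probe stayed between -0.0678 and 0.734, below the low-signal limit, on all arrays. The Y-linked Eif2s3y read 0.0435 and 0.162 in those 2 animals and at least 8.05 in the others, and Kdm5d read 1.25 and 1.16 against 1.76 to 2.44, while Uty lay below 0.684 throughout. Each genotype thus held 1 animal with that pattern, and none of the 5 measured genes of X inactivation and the Y chromosome passed (limma, adjusted p between 0.755 and 0.994), nor did any adjusted over the list alone. That list had too few complete members for camera. With only replicates 2 and 3 of each genotype, 4 of 12 female-biased genes fell and 0 rose, and 1 of 15 male-biased genes fell and 0 rose. With a term for replicate 1 of both genotypes, which is balanced and so mainly takes up variance, 6 of 14 female-biased genes fell and 0 rose, and 5 of 17 male-biased genes fell and 2 rose. That fit gave 1739 probes past the threshold, 1280 higher and 459 lower in mutant kidney. It also gave 7 citric acid cycle genes lower, 3 endothelial genes higher and 4 cell cycle genes higher, against 4, 1 and 2 in the main fit.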

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

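Every alternative below that concerns replicate 1, the low-signal limit, or values at or below 0 was chosen after the data were seen, and the others were fixed earlier. Probes lower in mutant kidney numbered 556 with quantile normalization, 550 with cyclic loess and 513 at adjusted p below 0.10, against 329 as reported. With no intensity trend in the variance, probes higher or lower numbered 191, higher 179 and lower 12, and 183 of the reported 1392 calls remained. With only replicates 2 and 3 of each genotype, probes higher or lower numbered 905 and higher 630, and 807 of the calls remained; fewer arrays were tested. Elsewhere the cause was not tested. With the replicate block 1856 probes passed and 1381 of the calls remained.

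Leaving out single arrays gave 743 to 1230 probes higher or lower, 589 to 1026 higher and 154 to 325 lower, with the smallest counts without homozygous mutant replicate 2. Gene lists shifted then numbered 17 to 21. With camera with estimated correlation, gene lists shifted numbered 0, higher 0 and lower 0, and by fry gene lists lower numbered 4; the cause was not tested.

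Over all alternatives run, 0 called lists and 0 called named genes reversed. The 20 shifted lists kept their call in 481 of 520 values, and 39 fell short of the threshold. Of the named genes called, 2693 of 3007 values kept the call and 314 did not. Endothelium had an adjusted p of 0.0629 with only probes above the low-signal limit in a genotype. Between 37.5% and 41.7% of the values of an array lay above that limit, and differences of named genes with a genotype mean below it are given as bounds.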

Other observations

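The gene families below and the first test of cell composition were chosen only after the results were seen. Genes were grouped by the stem of their symbol into 147 families with at least 10 members, of which 11 shifted (camera with Benjamini-Hochberg) and 0 with an estimated correlation, where the smallest adjusted p was 0.954. Other splits of the 6 arrays gave up to 2 families. By camera, collagens, Cxcl and Ccl chemokines and annexins shifted upwards, and solute carriers downwards with a median difference of -0.12. The direction was the same after quantile normalization, after cyclic loess and without each array in turn. Of the members, 5 of 10 Cxcl, 6 of 14 Ccl and 4 of 10 annexin genes rose. The fixed lists already held 13 of 33 collagen, 4 of 10 Cxcl, 3 of 14 Ccl and 3 of 10 annexin genes. These family shifts therefore partly repeat the list results. Of 33 collagens 14 rose and 1 fell, including Col14a1 (1.84 ± 0.22 log2 units), Col5a3 (1.79 ± 0.21) and Col18a1 (1.26 ± 0.16), which stood in no fixed list. Cxcl14 (2.01 ± 0.23), Ccl6 (2.00 ± 0.25), Ccl19 (1.77 ± 0.31) and Anxa6 (0.86 ± 0.14) rose as well.

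Of 260 solute carrier genes 16 fell and 3 rose, while 27 and 29 fell after quantile normalization and cyclic loess, 8 without homozygous mutant replicate 2, and 5 rose without wild type replicate 2. Outside the fixed lists, Slc18a1 (-1.09 ± 0.15 log2 units), Slc22a22 (-1.06 ± 0.19), Slc16a9 (-0.99 ± 0.19), Slc37a4 (-0.96 ± 0.14), Slc22a18 (-0.89 ± 0.16) and Slc16a13 (-0.69 ± 0.13) fell. The 3 that rose were Slc25a24 (1.94 ± 0.14), Slc38a2 (0.96 ± 0.15) and Slc41a1 (0.79 ± 0.15).

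Matrix (31 of 33), smooth muscle (9 of 14) and some myeloid genes (13 of 29) were higher, and some proximal tubule genes (11 of 31) lower. Fewer proximal tubule cells could produce such a pattern. None of these lists passed by camera with an estimated correlation (adjusted p between 0.082 and 0.102). A lower share of proximal tubule cells alone would raise markers of all other types alike. The least shifted of the 3 risen lists exceeded the mean of 6 lists of other kidney cell types by 0.8857 log2 (SE 0.105). The 3 lists were taken because they had risen, so the choice favoured a gap and the SE does not cover it. The gap is therefore given without a verdict. The 31 proximal tubule genes differed by unequal amounts (chi-square test of heterogeneity, n = 31 genes taken as independent and standard errors as known, p = 2.22e-05). That test addresses only a common fall of all members. Fewer proximal tubule cells, a gain of stromal and myeloid cells, and a change of transcription within cells stay open and may all contribute.

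More probes were higher than lower in mutants. The centring of each array on its median would need a share of higher calls of 60% or less under other scalings, and the lower share was 61.17%, after quantile normalization. Noise of dim probes would need as much among bright ones, where 71.29% of 1066 calls were higher. The first margin is narrow, so centring may account for part of the asymmetry.

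Replicate 1 of each genotype showed Xist signal and little Eif2s3y signal. Each genotype held 1 such animal, so the design sets this pattern equally against both means. A genotype effect that differs between sexes was not tested.

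Of the 10 splits of the 6 arrays into 3 and 3, 1 gave as many probes past the threshold, the real one (1392, highest other 0), and 1 gave as many gene lists (20, highest other 17). Splits are too few for a share under 0.05.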
